A study of Rattus norvegicus with 6 samples.

How the data were processed

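Total RNA from the non-tumor liver of 6 male Wistar rats was hybridized to Illumina bead arrays, 1 array per rat, as the labels describe. All had been injected once a week with DEN (diethylnitrosamine, 50 mg/kg) over 18 weeks. Of these rats, 3 drank 0.02% epigallocatechin gallate (EGCG) from week 13 to week 18 and 3 drank plain water. They were killed in week 19. The labels give 3 rats per group and end in a different number for each sample, taken here as the rat, so that no rat of one group is matched with a rat of the other.

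The authors deposited a table of bead intensities for 22523 probes, on a linear scale, with 1 column per rat. Its columns were neither background-subtracted nor normalized between arrays, as the values show: the lowest intensity was 53.4, and the array medians ran from 112 to 120. The authors also deposited a table of normalized intensities for the same probes. In that table, each column was a monotone function of the same rat's non-normalized column and the medians ran from 115 to 116, on a linear scale that was not centred. The method of that normalization, the scanner software and its version are not given in the sources used here. Neither table carried detection p-values, bead counts or negative control probes, so that no probe can be called detected or absent. No slide, hybridization or scan date was used, and a batch that follows the groups could not be tested.

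The analysis began from the non-normalized intensities. They were background-corrected with limma's normexp method with an offset of 50, quantile normalized and put on the log2 scale. The offset compresses the differences of dim probes. Probes whose mean over the 6 arrays lay below the 40th percentile (log2 6.39) were left out, which kept 13514 probes. Gene names came from the platform annotation, which gave 1 symbol for 13793 probes, several symbols for 0 and none for 8730. Probes with no symbol were tested but are named by their probe identifier only. No reference genome was used, so that no coordinates are given. Each named gene is represented by its brightest probe, which gave 9193 genes. Second probes were compared only for genes picked for the text by the rule below. Among these, the direction differed for Alb and was shared by Aldoa, Gstp1, Mup4l4, Rps9, Tie1 and Tm7sf2.

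Differences are EGCG minus water on the log2 scale. They were tested with limma (lmFit and eBayes with an intensity trend, two-sided), over all 6 arrays, without covariates, and Benjamini-Hochberg adjusted over the 13514 probes. The threshold was an adjusted p under 0.05. Standard errors (SE) are the moderated ones, and group values are means ± SD of 3 rats. Before the data were examined, the groups, the tests, the alternatives and the rule for named genes were set, and 43 gene lists were fixed for liver cell types, pathways and possible contaminating tissues, and each had at least 5 measured members. The lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 43 lists. Lists share members, so that their tests are not independent. Members were also adjusted over each list alone, and those counts are not adjusted for the number of lists. Camera with a correlation estimated from the data and limma's rotation test fry were alternatives. R 4.3.3 and limma 3.58.1 were used.

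The rule for the genes named in the text took the 10 largest increases and 10 largest decreases among genes past the threshold whose groups did not overlap. It added up to 4 members of each described list with the smallest unadjusted p, and 23 key genes whatever their value. Which lists are described, and whether 2, 3 or 4 of their members are named, was chosen after the results were seen. Of the key genes, Acta2, Mki67 and Cd68 had no probe under that symbol in the annotation used here. Other alternatives covered background correction, normalization, the filter, the variance model, array weights, a test without moderated variances (an ordinary t-test), the authors' normalized table and the omission of each rat in turn. The number of arrays limits the precision: an exact permutation test of 3 rats against 3 cannot give a two-sided p under 0.1.

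The scripts were tested on simulated data with 200 changed probes above log2 8 in each of 10 sets. Where the variances followed limma's model, 6.67% of probes changed by 0.5 on the log2 scale were recovered, 80.3% of those changed by 1 and 100% of those changed by 2, and 3.92% of all calls were false. With limma's moderated variance of each probe, 8.96% of calls were false. The unmoderated variance of each probe was not tried. Camera called the changed list in 10 of 10 sets and 0 of 200 unchanged lists. Every member of the changed list was raised by 0.5 or 1, so that smaller or partial changes of a list were not tried. Genes were simulated as independent, which real lists are not.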

Results

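Gene expression was measured in non-tumor liver from rats given repeated diethylnitrosamine, a hepatocarcinogen that is used to produce fibrosis, cirrhosis and liver tumors in rodents. The comparison asks which transcripts differ when epigallocatechin gallate (EGCG), the main catechin of green tea, is added to the drinking water for weeks 13 to 18. There were 3 EGCG rats (EGCG_228, EGCG_234 and EGCG_236) and 3 water rats (water_224, water_227 and water_237). The non-normalized mean intensity per array ran from 382 (water_237) to 531 (water_224), and the median from 112 to 120.

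The arrays were similar to one another. Pearson's r over 13514 probes was 0.983 ± 0.00424 (mean ± SD of 6 pairs) within groups and 0.976 ± 0.00453 (9 pairs) between groups. The first principal component held 39.9% of the variance. On it, the water rats lay at 14.1 to 15.3, EGCG_228 at -16.7 and EGCG_234 at -25.2, while EGCG_236 lay at -1.8, between the groups. EGCG_236 was about as similar to the water arrays (mean r 0.979) as to its own group (mean r 0.979). Its r was 0.983 with water_237 and 0.982 with water_227, above that with EGCG_228 (0.980) and EGCG_234 (0.979). With water_224 it was 0.973. At most 1 of the 22523 non-normalized values was identical between any pair of arrays.

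**Figure D1:**
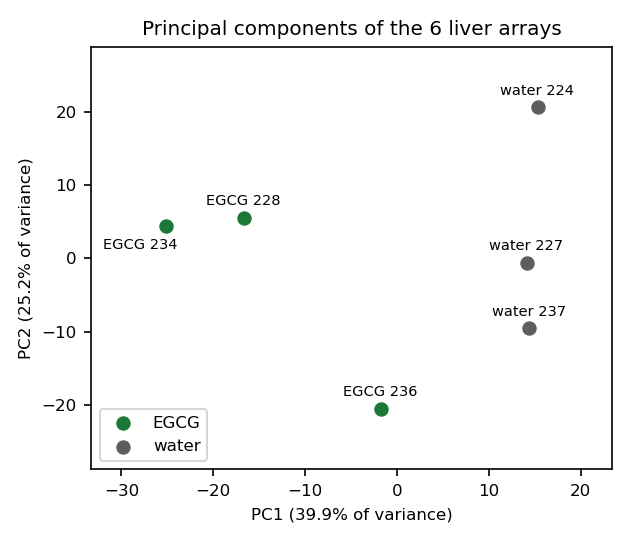
Each point is 1 rat's array, placed by its first 2 principal components over 13514 probes (arbitrary units; 39.9% and 25.2% of the variance), colored by group. On the first component the 3 water rats lie to the right, and EGCG_236 at -1.8 lies between them and the other EGCG rats. On the second, EGCG_236 (-20.5) is lowest and water_224 (20.6) highest.

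Among named genes past the threshold, each at its brightest probe, the largest decreases with EGCG included the connective tissue genes Ccn2 and Mgp and the hemoglobins, and the largest increases the major urinary proteins and Rps9. Of 9193 named genes, 52 passed the threshold (limma, adjusted p under 0.05), 41 lower and 11 higher with EGCG. Their changes ran from 1.53-fold to 10.1-fold, and the 2 groups of rats did not overlap for any of the 52. Another 12 probes without a gene name passed, 10 of them higher. Without the threshold, 1376 probes had an unadjusted p under 0.05, where chance would give 676, but another split of the 6 arrays, EGCG_228, EGCG_234 and water_224 against the rest, gave 1408. Over all named genes, 16.5% had groups that did not overlap, where chance gives 10%. The count depended on single rats: it was 8 without EGCG_228, 9 without EGCG_234, 11 without water_227, 34 without water_237 and 48 without water_224, and it rose to 158 without EGCG_236. Without EGCG_236, more genes were higher than lower (85 against 73).

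Among named genes at their brightest probe, the largest increases past the threshold belonged to the major urinary proteins, lipocalins that the male rat liver secretes. Over all probes, the unnamed ILMN_1365113 (log2 difference 4.31) and a second probe of Rps9 (3.68) exceeded them. Mup4 was 10.1-fold higher (log2 difference 3.33, SE 0.51, limma adjusted p = 0.0231), Mup4l4 9.17-fold (3.20, SE 0.54, adjusted p = 0.0306) and Mup5 6.79-fold (2.76, SE 0.47, adjusted p = 0.0326). Mup4 stood at log2 13.92 ± 0.75 with EGCG and 10.59 ± 1.16 with water (SD, n = 3 each). These genes have near-identical copies, and a probe can read several of them, so that the member that changed is uncertain. The aldo-keto reductases Akr1c3 (2.79-fold, adjusted p = 0.0046) and Akr1c2 (2.52-fold, adjusted p = 0.0197) rose as well, and they too belong to a family of similar sequences. Lipc, the hepatic lipase, rose 2.01-fold (adjusted p = 0.0426). Lect2, a chemotactic protein secreted by hepatocytes, rose 2.27-fold (adjusted p = 0.047). Rgs3, a regulator of G protein signaling, rose 2.42-fold (adjusted p = 0.0384), and Car5a, the mitochondrial carbonic anhydrase, 1.87-fold (adjusted p = 0.0412). Mup4, Mup4l4 and Mup5 lost their calls without EGCG_228, EGCG_234, water_227 or water_237 (adjusted p from 0.0691 to 0.153) and with a robust trend (0.244 to 0.303), and Akr1c2 without EGCG_228, EGCG_234 or water_227 (0.0593 to 0.0776). Lipc and Lect2 kept their calls only without EGCG_236, Rgs3 only without EGCG_228 and Car5a only without water_224, with adjusted p from 0.0507 to 0.211 when any other rat was left out. Median scaling ended the calls of Lipc, Lect2 and Car5a (0.154 to 0.179) and cyclic loess did too (0.051 to 0.07), while the fit without an intensity trend ended those of Mup4, Mup4l4, Mup5, Rgs3, Lect2 and Car5a (0.0511 to 0.0661). The stricter filter ended those of Mup4l4, Mup5, Rgs3, Lect2 and Car5a (0.0527 to 0.0602), and Lect2 also missed the threshold without background correction (0.0508) and with the authors' normalized values (0.0516).

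Rps9, a protein of the small ribosomal subunit, rose 4.33-fold at its brighter probe (ILMN_2038796; log2 2.11, SE 0.17, limma adjusted p = 0.000422). The values were 12.76 ± 0.21 with EGCG and 10.65 ± 0.15 with water (SD, n = 3 each). Its second probe (ILMN_2038795) differed by 3.68 (SE 0.19) on the log2 scale. The other ribosomal protein genes did not share this direction: of 68 measured, 1 rose (Rps9 itself) and 0 fell, and 53 had a log2 difference below 0. Adjusted over the list alone, 1 passed, again Rps9. The list was called lower (mean -0.088, camera adjusted p = 0.00316; adjusted p = 0.729 with an estimated correlation), a call lost without EGCG_228, EGCG_234 or water_237 (means -0.020, -0.028 and -0.034; adjusted p = 0.348, 0.211 and 0.202). Relative to the water mean, the list's mean was -0.22 in EGCG_228 and -0.21 in EGCG_234 but 0.17 in EGCG_236, the highest of the 6 rats; the difference was -0.22 without EGCG_236 and -0.14 without water_224.

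Among named genes past the threshold, the largest decreases were in connective tissue and blood transcripts. Ccn2, connective tissue growth factor, fell 3.81-fold (log2 -1.93, SE 0.24, limma adjusted p = 0.00976), from 11.66 ± 0.33 with water to 9.73 ± 0.43 with EGCG (SD, n = 3 each). Mgp, the matrix Gla protein, fell 3.77-fold (adjusted p = 0.0231). The hemoglobin genes Hbb-b1, Hbb and Hba-a1 fell 3.95-fold, 3.36-fold and 2.97-fold (adjusted p = 0.0391, 0.0332 and 0.00635). Hmox1, the heme oxygenase that degrades heme, fell 3.15-fold (adjusted p = 0.0197). Lcn2, a siderophore-binding protein of inflamed liver and neutrophils, fell 2.83-fold (adjusted p = 0.0412). Ms4a4a, a membrane protein of macrophages, fell 2.68-fold (adjusted p = 0.00635), the chemokine Ccl19 2.60-fold (adjusted p = 0.0231) and the calcium-binding S100a11 2.52-fold (adjusted p = 0.0197). Of these 20 genes, Rps9, Akr1c3, Ccn2, Hba-a1 and Ms4a4a passed the threshold under every alternative but the test without moderated variances, which called 0 genes (1164 probes at an unadjusted p under 0.05; limma called 52 genes). Among the decreases, Lcn2 lost its call when any 1 rat was left out (adjusted p from 0.051 to 0.157), and Hbb-b1 and Hbb without any rat but EGCG_236 (0.0723 to 0.137) and with a robust trend (0.146 and 0.0636). Mgp lost its call without EGCG_228, water_227 or water_237 (0.0609 to 0.0758), Hmox1 without EGCG_228, EGCG_234 or water_227 (0.0634 to 0.0776), and Ccl19 and S100a11 without EGCG_228, EGCG_234 or water_237 (0.0593 to 0.118). Lcn2 and S100a11 missed the threshold with median scaling (0.071 and 0.0548), and Lcn2, Hbb-b1 and Hbb with the stricter filter (0.0566 to 0.0602) and without an intensity trend (0.061 to 0.0672).

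**Figure D2:**
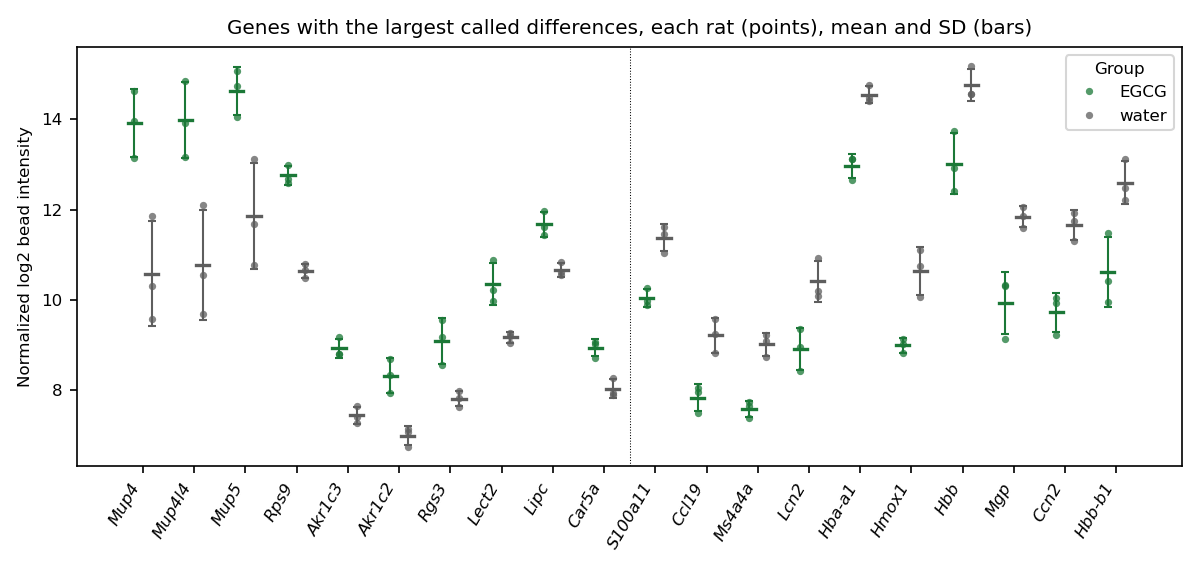
Normalized log2 bead intensity (vertical axis) of the 10 named genes with the largest increases (left of the dotted line) and the 10 with the largest decreases (right), for each rat (points), with the group mean and SD (bars, n = 3). Mup4 lies at 13.92 with EGCG and 10.59 with water, and Ccn2 at 9.73 and 11.66, with no overlap between groups for any gene shown.

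Of the 43 gene lists fixed in advance, 26 passed the set test (camera, preset correlation, adjusted p under 0.05), 18 lower and 8 higher with EGCG. With the correlation estimated from these 6 arrays, 0 lists passed (6 at an unadjusted p under 0.05, lowest adjusted p = 0.291), and fry called 0 for a shared direction and 18 for change in either direction. The list calls below therefore rest on the preset correlation, and the other p is given beside each. Estimated correlations ran from -0.165 (metallothioneins) to 0.672 (immediate early genes), with 0.155 for the matrix list, against the preset 0.01. At the preset correlation, other splits of the 6 arrays called from 4 to 22 lists. For 15 of the 26 called lists, the means of the EGCG rats did not overlap those of the water rats. For 6 lists, none of them called, the mean, the median and the test differed in sign: peroxide removal, glucose, circadian clock, autotaxin, iron and heme, and metallothioneins.

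Genes of the extracellular matrix were lower on average with EGCG. Of 28 measured members of the fibrosis list, 3 fell (Ccn2, Mgp and Dcn), 0 rose and 25 did not pass; adjusted over the list alone, 16 passed, all lower. Dcn, the collagen-binding proteoglycan decorin, fell by 1.07 on the log2 scale (SE 0.17, limma adjusted p = 0.0231). Dcn and Vim lost their calls without EGCG_228, EGCG_234 or water_227 (adjusted p from 0.0719 to 0.133) and with median scaling (0.103 and 0.131). Timp1, a metalloproteinase inhibitor, differed by -0.87 (adjusted p = 0.0615), Col1a2 by -0.66 (adjusted p = 0.166) and Col1a1 by -0.47 (adjusted p = 0.266), none past the threshold. Timp1 passed without EGCG_236 (-0.92, adjusted p = 0.037), with a robust trend (0.0404) and with array weights (0.0264). The list's mean was -0.53 (camera adjusted p = 1.11e-11; adjusted p = 0.291 with an estimated correlation). In the stellate cell and myofibroblast list, 1 of 13 members fell, the intermediate filament gene Vim (-1.18, SE 0.18, adjusted p = 0.0231), and 5 passed over the list alone. Tagln and Actg2, contractile genes of smooth muscle and myofibroblasts, differed by -0.95 and -0.66 (adjusted p = 0.0917 and 0.0836), and Cygb by -0.59 (adjusted p = 0.193). Actg2 passed without EGCG_236 (-0.81, adjusted p = 0.015) and with array weights (0.0182), and Tagln with median scaling (0.0499) and with array weights (0.0417). The mean was -0.40 (camera adjusted p = 3.64e-05; adjusted p = 0.291 with an estimated correlation). In the TGF-beta list, 1 of 16 members fell, again Ccn2; Ltbp1 differed by -0.54 (adjusted p = 0.209) and Tgfb1 by -0.54 (adjusted p = 0.39; -0.27 without water_224). That list's call (mean -0.22, camera adjusted p = 0.0295; adjusted p = 0.583 with an estimated correlation) was lost without EGCG_236, water_224 or water_237 (adjusted p = 0.0723, 0.253 and 0.0688) and on ranks (0.0718). Adjusted over the list alone, 2 of its members passed. In the same samples, pancreas and adipose tissue markers had a mean of -0.46 (camera adjusted p = 0.0073; adjusted p = 0.291 with an estimated correlation), beside these lists and those of vessels and bile ducts, a call lost without the filter (mean -0.22, adjusted p = 0.0868).

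Vessel and bile duct markers were lower on average too. In the endothelial list, 1 of 12 members fell, Vwf, von Willebrand factor (-0.84, SE 0.14, limma adjusted p = 0.0332), and 4 passed over the list alone. Vwf lost its call without any rat but EGCG_236 (adjusted p from 0.0781 to 0.13) and with median scaling (0.117). Emcn differed by -0.81 (adjusted p = 0.144), Tie1 by -0.54 (adjusted p = 0.263; -0.36 without water_224) and Sox18 by -0.39 (adjusted p = 0.214). The list's mean was -0.31 (camera adjusted p = 0.000296; adjusted p = 0.291 with an estimated correlation). In the cholangiocyte list, 0 of 14 members passed, and 5 passed over the list alone. The keratins Krt19 and Krt7 differed by -1.39 (SE 0.37, adjusted p = 0.172) and -0.38 (adjusted p = 0.227), Tspan8 by -1.04 (adjusted p = 0.0917) and Cd24 by -0.82 (adjusted p = 0.249). The mean was -0.38 (camera adjusted p = 0.000296; adjusted p = 0.311 with an estimated correlation). Muscle and mesothelium genes (mean -0.21, 0 of 10 passed, 2 over the list alone) had a camera adjusted p = 0.0466, and an adjusted p = 0.639 with an estimated correlation. That call was lost without EGCG_228, EGCG_234, water_224 or water_237 (adjusted p = 0.193, 0.107, 0.253 and 0.0887), and also without background correction, without the filter, on ranks and with the authors' normalized values (0.0529 to 0.14); without the filter the mean was -0.14.

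Inflammatory transcripts fell in part. Of 24 cytokines and chemokines, 2 fell, Ccl19 and the neutrophil chemokine Cxcl1 (-1.14, SE 0.19, limma adjusted p = 0.0304), and 0 rose; adjusted over the list alone, 7 were lower and 3 higher. Cxcl1 lost its call without EGCG_228, EGCG_234, water_224 or water_227 (adjusted p from 0.0625 to 0.145) and with median scaling (0.0686). Ccl21 differed by -1.22 (adjusted p = 0.141), Ccl2 by -0.48 (adjusted p = 0.276), Tnf by -0.028 (adjusted p = 0.955) and Cxcl11 by 0.79 (adjusted p = 0.115). Ccl21 passed without water_224 (-1.54, adjusted p = 0.0362) and with median scaling (0.0423). The list's mean was -0.28 (camera adjusted p = 0.00213; adjusted p = 0.311 with an estimated correlation). Of 8 neutrophil genes, 1 fell, Lcn2, which hepatocytes also make, and 3 passed over the list alone. S100a8 differed by -1.32 (adjusted p = 0.0893), Camp by -0.32 (adjusted p = 0.295) and Defa5 by -0.30 (adjusted p = 0.462; -0.19 without water_227). S100a8 passed without water_237 (-1.72, adjusted p = 0.0093) and with array weights (0.0296). The mean was -0.46 (camera adjusted p = 0.00236; adjusted p = 0.291 with an estimated correlation). Of 17 macrophage and Kupffer cell genes, 0 passed. Over that list alone 1 was higher, the scavenger receptor Marco (1.03, SE 0.25, adjusted p = 0.131 over all probes), while Cd14, C1qc and Fcer1g differed by -0.69, -0.48 and -0.44 (adjusted p = 0.23, 0.39 and 0.427). Marco passed without EGCG_236 (1.27, adjusted p = 0.0368). The macrophage mean was -0.19 (camera adjusted p = 0.00137; adjusted p = 0.305 with an estimated correlation), and -0.12 without water_224 (adjusted p = 0.0225). The 7 MHC class II genes had a mean of -0.27 (0 passed over all probes or over the list alone), with RT1-Ba at -0.56 (adjusted p = 0.359; -0.37 without EGCG_228) and RT1-Db1 at -0.39 (adjusted p = 0.542; -0.22 without EGCG_234). Their camera adjusted p = 0.00405, and adjusted p = 0.3 with an estimated correlation. Lymphocyte genes (19 measured, mean -0.018, camera adjusted p = 0.844) and interferon response genes (24 measured, mean 0.017, camera adjusted p = 0.894) did not pass.

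Of 10 red cell and platelet genes, 3 fell, the hemoglobins named above, and 6 passed over the list alone. Pf4, a platelet chemokine, differed by -0.69 (SE 0.17, limma adjusted p = 0.141). The mean was -0.78 (camera adjusted p = 2.72e-06; adjusted p = 0.291 with an estimated correlation). The same EGCG samples gave all comparisons of liver genes.

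Among markers of fetal and preneoplastic liver, 0 of 20 passed over all probes; over the list alone, 8 were lower and 2 higher. Gpc3, the oncofetal glypican 3, differed by -0.80 (SE 0.22, limma adjusted p = 0.184), the aldo-keto reductase Akr1b7 by -1.85 (adjusted p = 0.237) and Anxa2 by -0.66 (adjusted p = 0.123). Gpc3 passed without EGCG_236 (-1.06, adjusted p = 0.0161), Akr1b7 without water_237 (-2.65, adjusted p = 0.0374), and Gpc3 and Anxa2 with array weights (0.0417 and 0.0447). Gstp1, the placental glutathione transferase of rat preneoplastic foci, differed by -0.48 (adjusted p = 0.706) and Afp, alpha-fetoprotein, by 0.19 (adjusted p = 0.792). Gstp1 stood at -0.16 without EGCG_228, -0.26 without water_237, -0.78 without water_224 and -0.90 without EGCG_236, and Afp at 0.082 without water_237 and 0.34 without water_224. The list's mean was -0.36 (camera adjusted p = 0.00236; adjusted p = 0.291 with an estimated correlation). Tspan8 and Cd24 are among the members it shares with the cholangiocyte list. Of 39 cell cycle genes, 0 passed over all probes or over the list alone (mean 0.10, camera adjusted p = 0.0807). The list passed without EGCG_228, EGCG_236 or water_237 (means 0.13, 0.13 and 0.20; adjusted p = 0.0279, 0.0431 and 0.000163) and with median scaling (0.079; adjusted p = 0.0464), and its mean was lowest without EGCG_234 (0.050). Ccnd1, cyclin D1, differed by 0.93 (adjusted p = 0.27), Cdkn3 by 0.74 (adjusted p = 0.208) and Kif20a by 0.56 (adjusted p = 0.209).

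**Figure D3:**
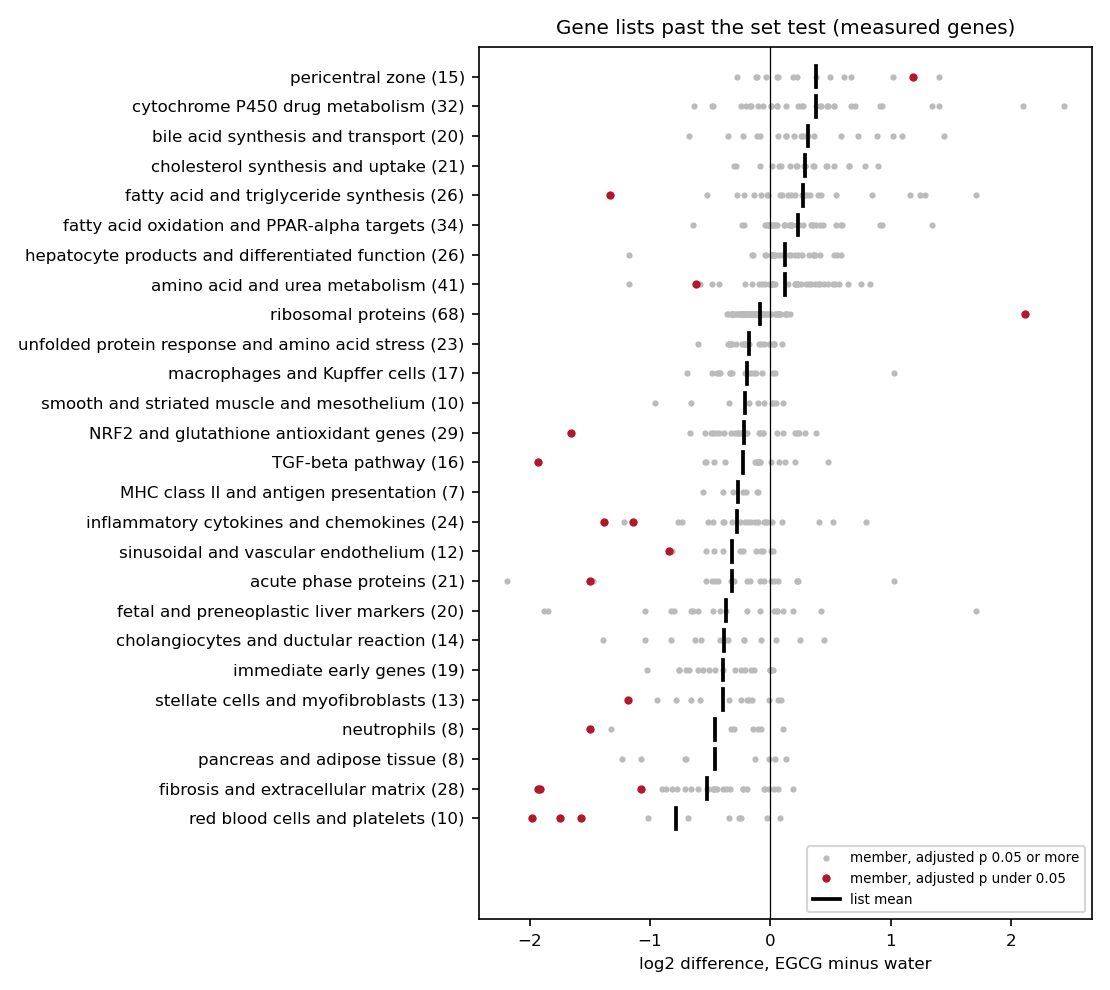
Log2 difference between EGCG and water (horizontal axis) for each measured member (points, red where the adjusted p is under 0.05) and the mean (black bars) of the 26 gene lists past the set test, with the number of measured genes in parentheses. The red cell and matrix lists have the lowest means, -0.78 and -0.53, and Rps9 at 2.11 stands apart from the other ribosomal proteins.

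Of 29 NRF2 and glutathione genes, 1 fell, Hmox1, and 1 passed over the list alone. Txnrd1, thioredoxin reductase, differed by -0.67 (SE 0.26, limma adjusted p = 0.382), Gpx2 by -0.54 (adjusted p = 0.338), Cbr3 by -0.27 (adjusted p = 0.403) and Nqo1 by -0.32 (adjusted p = 0.678). Without EGCG_234, Txnrd1 stood at -0.33 and Nqo1 at -0.11, and Nqo1 at -0.20 without water_237. The list's mean was -0.22 (camera adjusted p = 0.00316; adjusted p = 0.512 with an estimated correlation), and its call was lost without EGCG_234 (mean -0.11, adjusted p = 0.151). In the unfolded protein response list, 0 of 23 passed over all probes or over the list alone (mean -0.18, camera adjusted p = 0.00316; adjusted p = 0.488 with an estimated correlation). Its call was lost without water_224 (mean -0.10, adjusted p = 0.0817), and without water_237 the mean was -0.27. Pdia6, Pdia3 and Edem1 differed by -0.34, -0.33 and -0.33 (adjusted p = 0.561, 0.541 and 0.375), and Pdia6 by -0.17 without EGCG_236. Of 19 immediate early genes, which respond to handling and tissue collection within minutes, 0 passed over all probes or over the list alone. Fos differed by -1.03 (adjusted p = 0.562), Ccn1 by -0.70 (adjusted p = 0.217) and Nr4a3 by -0.51 (adjusted p = 0.403), and without water_224 Fos stood at -0.16 and Nr4a3 at -0.22. Their mean of -0.39 (camera adjusted p = 0.00341; adjusted p = 0.639 with an estimated correlation) rested on water_224, without which it was 0.051 (adjusted p = 0.82); it was -0.60 without water_227 and -0.64 without water_237. Of 21 acute phase genes, 1 fell, Lcn2, while A2m, alpha-2-macroglobulin, differed by -2.19 (SE 0.55, adjusted p = 0.142), and passed without water_237 (-3.10, adjusted p = 0.000115). Adjusted over the list alone, 4 were lower and 1 higher. Their call (mean -0.32, camera adjusted p = 0.00711; adjusted p = 0.639 with an estimated correlation) was lost without EGCG_236, water_224 or water_227 (adjusted p = 0.484, 0.11 and 0.0703) and with median scaling (0.171). The mean was -0.17 without EGCG_236 and -0.50 without water_237.

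Genes of sterol and bile acid metabolism were higher on average. Of 21 genes of cholesterol synthesis and uptake, 0 passed over all probes, 18 had a log2 difference above 0 and 1 passed over the list alone. Fdft1, squalene synthase, differed by 0.78 (SE 0.19, limma adjusted p = 0.13), Tm7sf2 by 0.89 (adjusted p = 0.261; 0.59 without water_224), Sc5d by 0.47 (adjusted p = 0.281) and Cyp51 by 0.36 (adjusted p = 0.249). The mean was 0.29 (camera adjusted p = 0.00023; adjusted p = 0.305 with an estimated correlation). Of 20 bile acid genes, 0 passed over all probes and 6 passed over the list alone, all higher. The bile acid-CoA ligase Slc27a5 differed by 1.44 (adjusted p = 0.209), the conjugating enzyme Baat by 0.73 (adjusted p = 0.112), Amacr by 0.89 (adjusted p = 0.144) and the uptake transporter Slco1b2 by 1.02 (adjusted p = 0.0894). Slc27a5 passed without EGCG_236 (2.04, adjusted p = 0.00218) and Slco1b2 without water_224 (1.26, adjusted p = 0.0207). With array weights Slc27a5, Slco1b2, Baat and Fdft1 passed (adjusted p from 0.0304 to 0.0438). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.066 (SE 0.38, adjusted p = 0.977), from -0.39 without EGCG_236 to 0.42 without EGCG_228. The mean was 0.32 (camera adjusted p = 0.000362; adjusted p = 0.291 with an estimated correlation). In the same EGCG samples the matrix list had a mean of -0.53 and the red cell list -0.78, beside these and the other metabolic lists.

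Of 34 genes of fatty acid oxidation and PPAR-alpha, 0 passed over all probes or over the list alone. Cpt1a, which admits fatty acids to mitochondria, differed by 0.93 (SE 0.26, limma adjusted p = 0.201), Cyp4a2 by 1.34 (adjusted p = 0.338), Fabp1 by 0.59 (adjusted p = 0.239) and Acadm by 0.55 (adjusted p = 0.348). Without EGCG_236, Cyp4a2 (2.08, adjusted p = 0.00104), Fabp1 (0.76, adjusted p = 0.031) and Acadm (0.74, adjusted p = 0.0394) passed, while Cyp4a2 stood at 0.86 without EGCG_234 (adjusted p = 0.761). Their call (mean 0.23, camera adjusted p = 0.00236; adjusted p = 0.665 with an estimated correlation) was lost without EGCG_234 or water_237 (adjusted p = 0.199 and 0.108). Relative to the water mean, the list stood at 0.37 in EGCG_228 and 0.51 in EGCG_234 but at -0.20 in EGCG_236, below every water rat (lowest -0.14), and its difference ran from 0.086 without EGCG_234 to 0.44 without EGCG_236. In the fatty acid and triglyceride synthesis list, 1 of 26 members fell, Lpl, lipoprotein lipase, which hydrolyzes circulating triglyceride (-1.33, SE 0.20, adjusted p = 0.0231). Lpl lost its call without EGCG_228, EGCG_234, water_227 or water_237 (adjusted p from 0.0621 to 0.0898) and with median scaling (0.0585). Over that list alone, 6 were higher and 2 lower, and Fads1, a fatty acid desaturase, differed by 1.16 (adjusted p = 0.172), and passed without water_237 (1.61, adjusted p = 0.0128). Its mean was 0.27 (camera adjusted p = 0.0121; adjusted p = 0.311 with an estimated correlation), a call lost without EGCG_234 or water_224 (adjusted p = 0.06 and 0.0961). In the pericentral list, 1 of 15 members rose, Lect2, and 2 passed over the list alone; Cyp1a2 differed by 1.40 (adjusted p = 0.284) and Rgn by 0.49 (adjusted p = 0.434; 0.28 without water_237). Cyp1a2 passed without EGCG_236 (2.05, adjusted p = 0.0133) and stood at 0.81 without EGCG_234 (adjusted p = 0.664). The pericentral mean was 0.38 (camera adjusted p = 0.00236; adjusted p = 0.305 with an estimated correlation), and the 13 periportal genes did not pass (mean 0.072, camera adjusted p = 0.44; 0.29 and adjusted p = 0.00341 without EGCG_236). The difference between the pericentral and periportal lists was not tested.

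Of 32 drug-metabolizing cytochrome P450 genes, 0 passed; over the list alone, 2 were higher and 1 lower. The male-specific Cyp2c11 and Cyp3a2 differed by 2.44 (SE 0.61, limma adjusted p = 0.142) and 2.10 (SE 0.57, adjusted p = 0.181). Cyp2f4 differed by 0.42 (adjusted p = 0.267), Cyp1b1 by -0.63 (adjusted p = 0.0955), Cyp2e1, which activates diethylnitrosamine, by 0.67 (adjusted p = 0.457) and Cyp1a1 by -0.20 (adjusted p = 0.864). Without EGCG_236, Cyp2c11 (3.21, adjusted p = 0.015), Cyp3a2 (2.87, adjusted p = 0.00722), Cyp2e1 (1.06, adjusted p = 0.0168) and Cyp1b1 (-0.75, adjusted p = 0.0403) passed, and with array weights Cyp2c11, Cyp3a2 and Cyp1b1 did (0.0253 to 0.0374). Cyp2e1 stood at 0.44 without EGCG_228, and Cyp1a1 ran from -0.52 without water_237 to 0.093 without water_227. Their mean was 0.38 (camera adjusted p = 0.00316; adjusted p = 0.639 with an estimated correlation), and the call was lost without EGCG_228 or water_237 (adjusted p = 0.0823 and 0.12). Relative to the water mean, EGCG_228 and EGCG_234 both stood at 0.60 and EGCG_236 at -0.055, within the water rats (-0.12 to 0.16), and without EGCG_236 the difference was 0.60. In the list of growth hormone dependent and sex-biased genes, 1 of 21 members rose (Mup5) and 1 fell, the insulin-like growth factor carrier Igfbp3 (-1.02, SE 0.17, adjusted p = 0.0306). Igfbp3 lost its call without any rat but EGCG_236 (adjusted p from 0.0678 to 0.156) and with median scaling (0.109). Igfbp1 differed by -3.09 (SE 0.67, adjusted p = 0.0917), and over the list alone 6 were higher and 2 lower. Igfbp1 passed without water_224 (-2.11, adjusted p = 0.0315) or water_237 (-3.94, adjusted p = 0.0203), without the filter (0.0469) and with array weights (0.0417). The list as a whole did not pass (mean 0.27, camera adjusted p = 0.163), but did without EGCG_236 or water_224 (0.45 and 0.48; adjusted p = 0.00745 and 0.00358); it stood at 0.15 without EGCG_234, 0.17 without water_227 and 0.16 without water_237. Fry called this list for change in either direction (adjusted p = 0.0313).

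Of 26 genes of hepatocyte products and function, 21 had a log2 difference above 0, and 0 passed over all probes or over the list alone. Albumin (Alb) differed by 0.065 (SE 0.19, limma adjusted p = 0.951; -0.063 at its second probe), Ttr by 0.53 (adjusted p = 0.295; 0.71 and adjusted p = 0.0405 without EGCG_236) and Tat, tyrosine aminotransferase, by -1.17 (adjusted p = 0.203; -0.69 without water_224). Leaving out 1 rat moved albumin from -0.063 (EGCG_236) to 0.21 (water_237). Their call (mean 0.12, camera adjusted p = 0.0109; adjusted p = 0.639 with an estimated correlation) was lost without EGCG_228, EGCG_234 or water_237 (means 0.066, 0.068 and 0.056; adjusted p = 0.14, 0.0736 and 0.197). Relative to the water mean, EGCG_228 and EGCG_234 both stood at 0.24 and EGCG_236 at -0.11, within the water rats (-0.14 to 0.091), and without EGCG_236 the difference was 0.24. In the amino acid and urea list, 1 of 41 members fell, Phgdh, the first enzyme of serine synthesis (-0.62, SE 0.11, adjusted p = 0.0429), which lost its call when any 1 rat was left out (0.051 to 0.172) and without an intensity trend (0.059). Over the list alone 3 were lower and 1 higher, and Bcat2 differed by -0.48 (adjusted p = 0.183). Its mean was 0.12 (camera adjusted p = 0.0371; adjusted p = 0.729 with an estimated correlation), a call lost without EGCG_228, EGCG_234, water_224 or water_237 (adjusted p = 0.411, 0.522, 0.215 and 0.223) and without the filter (0.0527). For that list EGCG_228 and EGCG_234 stood at 0.28 and 0.31 and EGCG_236 at -0.22, below every water rat (lowest -0.072), and the difference was 0.29 without EGCG_236, 0.045 without EGCG_228 and 0.030 without EGCG_234.

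Lysophosphatidic acid and EGF signaling lists did not pass. Enpp2, autotaxin, the enzyme that makes lysophosphatidic acid, differed by 0.83 (SE 0.20, limma adjusted p = 0.13; 12.95 with EGCG, 12.12 with water) and was the 1 member past the threshold over the list alone. Pla1a differed by -0.40 (adjusted p = 0.427). The 9 measured members had a mean of -0.033, a median of 0.097 and a camera adjusted p = 0.961, while fry called them for change in either direction (adjusted p = 0.0487). Egf differed by 0.31 (adjusted p = 0.434), Ereg by 0.32 (adjusted p = 0.355) and the receptor Egfr by 0.24 (adjusted p = 0.644; 0.14 without EGCG_228 and 0.42 without EGCG_236). The 7 EGF family genes had a mean of 0.12 (camera adjusted p = 0.0844), which was 0.074 without EGCG_234 (adjusted p = 0.215) and 0.050 without water_227 (adjusted p = 0.435). The camera adjusted p was 0.0987 for oxidative phosphorylation (66 genes), 0.293 for the p53 response (18 genes), 0.331 for apoptosis (19 genes), 0.549 for autophagy and lysosome (20 genes), 0.702 for peroxide and superoxide removal (15 genes) and 0.99 for metallothioneins and zinc transport (6 genes). Oxidative phosphorylation (mean 0.043) passed without water_227 (mean 0.076, adjusted p = 0.00954) and with median scaling (0.036, adjusted p = 0.0464). Its mean was -0.0080 without water_224 and 0.022 without EGCG_236 (camera adjusted p = 0.922 and 0.43).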

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

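Over 17 settings, the 27 named genes past the threshold kept their direction in each, and 5 of them stayed past the threshold in all but the ordinary t-test. Against 52 genes (11 higher, 41 lower), array weights gave 141 (53 and 88), the fit without an intensity trend 34 (6 higher) and the ordinary t-test 0 (0 and 0). Higher genes numbered 7 with median scaling and 6 with the stricter filter, which tests fewer probes. Leaving out 1 rat gave 8 to 158 genes, 2 to 85 higher and 5 to 73 lower, with 85 and 73 both without EGCG_236; each such fit leaves 2 rats in a group and assumes that they vary like the others. Array weights were lowest for EGCG_236 (0.494). With the authors' normalized values, 51 genes passed, 49 of them among the 52. The cause of the other shifts was not tested. The 26 lists became 0 with an estimated correlation and 0 with fry, and 19 to 28 when 1 rat was left out; 13 lists passed in the other 12 settings. Among values that did not pass, Cyp7a1 became -0.14 with array weights, and leaving out 1 rat turned the direction for Cyp7a1 (-0.39 to 0.42), Alb (-0.063 to 0.21), Cyp1a1 (-0.52 to 0.093) and Tnf (-0.036 to 0.022). List tests turned direction for autotaxin (means -0.051 with median scaling, -0.033 with fry), interferon (0.0030 without the filter), iron and heme (-0.0022 with fry), glucose (0.051 with ranks) and metallothioneins (-0.053 with ranks). When 1 rat was left out, these means ran from -0.062 to -0.00052, -0.053 to 0.10, -0.022 to 0.0087, -0.064 to 0.20 and -0.11 to 0.00085. The list tests also turned for the periportal (-0.036 to 0.29), circadian (-0.20 to 0.10), lymphocyte (-0.057 to -0.00068) and immediate early lists (-0.64 to 0.051). The values of dim probes carry the least information, since no detection call was used. No paired analysis was possible because the rats' numbers are not shared between the groups.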

Other observations

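The tests of Rps9 under the normalization and of the splits of the lists were set out before their results were seen, and the other tests in this part were chosen afterwards. Iron and heme genes went both ways: they did not pass for a shared direction (20 measured, mean -0.0022, camera adjusted p = 0.961), but fry called them for change in either direction (adjusted p = 0.0141). Of these, 1 fell, Hmox1, and 3 were higher and 2 lower when adjusted over the list alone. The transferrin receptor Tfrc differed by -0.57 (limma adjusted p = 0.142), Hjv, a regulator of hepcidin, by 0.68 (adjusted p = 0.235) and Alad, of heme synthesis, by 0.70 (adjusted p = 0.263). Tfrc passed without water_237 (-0.76, adjusted p = 0.0426) and Alad without EGCG_236 (0.96, adjusted p = 0.0261). Glucose genes went both ways too (24 measured, mean 0.051, median -0.056, camera adjusted p = 0.853; fry for either direction, adjusted p = 0.0244). The liver pyruvate kinase Pklr differed by 1.10 (adjusted p = 0.105; 0.0439 with array weights) and glycogen synthase Gys2 by 0.65 (adjusted p = 0.239), against -0.77 for Aldoa (adjusted p = 0.139) and -0.49 for Pfkp (adjusted p = 0.192), forms that many tissues use. Over that list alone, 3 were higher and 2 lower, and without EGCG_236 it passed (mean 0.20, adjusted p = 0.0442).

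Markers of pancreas and adipose tissue were lower on average with EGCG (8 measured, mean -0.46, camera adjusted p = 0.0073; adjusted p = 0.291 with an estimated correlation), and 4 passed over the list alone. The call was lost without the filter (mean -0.22, adjusted p = 0.0868). Cpa1 and Cela1, pancreatic enzymes, differed by -1.23 and -0.70 (limma adjusted p = 0.16 and 0.239), and the adipocyte genes Fabp4 and Cfd by -1.07 and -0.71 (adjusted p = 0.227 and 0.183; Fabp4 -0.70 without water_224). Cpa1 passed without water_224 (-1.60, adjusted p = 0.0248) and with median scaling (0.0468), and Cela1 without water_227 (-0.99, adjusted p = 0.0478). Clock genes did not pass (12 measured, camera adjusted p = 0.921), with Per1 at -0.98, Nfil3 at -0.62 and Nr1d1 at 0.62 (adjusted p = 0.371, 0.63 and 0.554). Without water_224, Per1 stood at -0.42 and Nfil3 at -0.10, and Nfil3 at -1.04 without water_237; Nr1d1 stood at 0.30 without EGCG_234 and 0.99 without EGCG_236. Heat shock genes did not pass (13 measured, mean -0.13, camera adjusted p = 0.186). Their mean was -0.20 without water_224 and -0.067 without water_227 (camera adjusted p = 0.0225 and 0.626). The small heat shock protein Cryab stood at -1.01 (limma adjusted p = 0.0517) and Bag3 at -0.21 (adjusted p = 0.697). Cryab passed in 7 of 17 other settings (adjusted p from 0.0178 to 0.0481), 2 of them without a rat (EGCG_236 or water_224).

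With 3 rats against 3 there are 10 splits of the 6 arrays, too few for a share under 0.05. The real split called 52 genes and the highest other 1, and 1 of the 10 splits, the real one, gave as many. For lists, the real split called 26 and the highest other 22, and again only the real one gave as many. The split that called 22 lists set EGCG_228, EGCG_234 and water_227 against the rest. Probes at an unadjusted p under 0.05 numbered 1376 in the real split and 1408 in the split of EGCG_228, EGCG_234 and water_224 against the rest.

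Rps9 is the pattern a biologist might look at first. At probe ILMN_2038795 the EGCG rats had non-normalized intensities of 3119, 2759.5 and 3662, and the water rats 259, 309.7 and 248. The unnamed probe ILMN_1365113, chosen after its values were seen, showed a larger contrast in the same direction (4683, 4347 and 6369 against 300.4, 308 and 244). Its normalized log2 difference was 4.31, against 3.68 for ILMN_2038795. Another unnamed probe, ILMN_1365787, differed by 2.08, with a range under 1 within each group. Normalization is argued against by the non-normalized log2 values of ILMN_2038795, which differed by 3.54 (SE 0.154), and a rise shared by ribosomal proteins by the median of the other 67, which was -0.122 (highest 0.167). A sequence difference between outbred rats under the probes and an effect of EGCG stay open. A batch that follows the groups could not be tested. The smallest gap between an EGCG and a water rat was 3.28 on the log2 scale, against a range within groups of at most 0.544. But each group falls wholly on 1 side, and no probe sequence was used.

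The lower matrix, stellate, vessel and bile duct lists may reflect a smaller share of non-hepatocyte cells in the EGCG samples, in which case macrophage genes would fall alike. Among members above log2 8, macrophage genes differed by -0.203 (SE 0.114, 11 genes). The difference from them was -0.619 (SE 0.184) for 12 matrix genes and -0.563 (SE 0.147) for 4 stellate genes. Without Marco, the macrophage gene that was higher, these differences were -0.496 (SE 0.157) and -0.439 (SE 0.123). Without water_224 the macrophage value was -0.115 and these differences -0.611 (SE 0.237) and -0.600 (SE 0.183). The stellate difference was -0.425 (SE 0.16) without Vim, -0.503 (SE 0.198) without Tagln and -0.556 (SE 0.0982) without Sparcl1. Without Reln it was -0.767 (SE 0.179), so that Reln fell less than the other stellate members. The matrix difference was -0.519 (SE 0.171) without Ccn2 and -0.52 (SE 0.16) without Mgp, the members that fell most. Leaving out Ccn2, Mgp and Marco together was not tried. Fn1 (-0.193) and Col14a1 (0.0267) fell no further than the macrophage mean. With all rats in, the mean of the matrix list argues against a loss equal to that of macrophages as the whole cause. The stellate mean does so less firmly. Without water_224 or water_237 (-0.541, SE 0.215), the matrix difference was too imprecise to decide this. No other cell type served as the reference. The macrophage list, fixed in advance, did not hold Ms4a4a, a macrophage gene among the largest decreases named above. Above log2 8, MHC class II genes differed by -0.299 (SE 0.102, 6 genes) and neutrophil genes by -1.41 (SE 0.338, 2 genes). An equal loss stays open for vessel genes (-0.219, SE 0.0526, but -0.0959, SE 0.0498 without Marco, with members from -0.84 for Vwf to 0.021 for Lyve1) and for bile duct genes (-0.263, SE 0.218; -0.140 without Marco, -0.444, SE 0.157, without EGCG_228 and -0.109, SE 0.198, without EGCG_234). Normalization is argued against for the matrix list, whose mean was -0.547 with median scaling. A change in the share of connective tissue or vessels, its sampling (pancreas and adipose markers were lower in the same samples, with a mean of -0.46), and expression within its cells stay open, as does EGCG as their cause.

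The lower hemoglobin transcripts could come from less blood in the EGCG samples. The 3 hemoglobin genes differed by -1.77 on average, and Ahsp, a chaperone of alpha hemoglobin chosen after its values were seen, by -1.02 (SE 0.588). The difference between them was -0.749 (SE 0.461), and ran from -1.06 (SE 0.439) without water_224, where Ahsp stood at -0.515, to -0.492 (SE 0.494) without EGCG_234 and -0.401 (SE 0.390) without water_237, too imprecise to tell whether they fell alike. Blood content, red cell maturity and an effect of EGCG cannot be told apart for these genes.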
